A study of Mus musculus with 152 samples.

How the data were processed

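Liver RNA of control-fed and LIDPAD-fed C57BL/6J mice was sequenced after TRIzol and column extraction, and the libraries were prepared by a sequencing company, per the labels' protocols. The authors' deposited signal values are FPM, gene counts divided by a size factor per column and expressed per 1000000, in 7 tables, 1 per feeding duration, of 54532 Ensembl genes, of which 54409 had a symbol. HISAT2, featureCounts, DESeq2 and the assembly GRCm38 are named, per the submitters' processing notes, without their roles, versions, annotation, strand setting or filters. The values of a column are whole multiples of 1 step, and 100% of values came out as whole reads within 0.02 reads, including 4 columns with a step close to 0.1 FPM that were used in the same way. Column totals ran from 751451 to 1289800 FPM. Mitochondrial ribosomal RNA took 18.3 to 30.2% of a library's reads.

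The labels listed 152 samples, but blocks of 4 consecutive columns differed by no more than sampling noise allows for parts of a single library. This was measured as chi-square per gene over genes with 200 to 2000 pooled reads, and columns under 2.5 were merged. Values of 2 reads were 5.35 times as common as values of 1 read, so counted reads came largely in pairs, for which sampling alone gives a chi-square near 2. The design fixed beforehand named all deposited samples, and merging them to 38 libraries departs from it because parts of a library are no replicates. The closing section gives the counts with each column as its own sample. Depth was 10.9 to 53.8 M (1000000 reads) per library, so the precision of low genes differs between weeks.

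Each week was fitted alone with limma 3.58.1 (R 4.3.3) on log2(mean FPM of the library + 0.5), with empirical Bayes moderation and a mean-variance trend, two-sided, on genes with at least 1 FPM in as many libraries as the smaller group holds. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. In weeks 1 to 12 each group held 2 libraries, so calls rest on the spread shared across genes. Lists of genes, 32 in number, were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, and again with the correlation estimated. Differences between weeks were tested in a joint limma fit of 14 group means, by an F test and 3 contrasts. Count tests on the recovered whole reads called 265, 40, 670, 2073, 3948, 3862 and 1181 genes from week 1 to week 48 with edgeR 4.0.16 (quasi-likelihood) and 480, 308, 1264, 2044, 3933, 4575 and 2424 with DESeq2 1.42.0. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions came from the GENCODE annotation of GRCm38.

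The tests, lists, named genes and most alternatives were chosen before the data were examined. Named genes are 30 index genes followed in every week (1 is not reported here), the 5 largest rises and 5 largest falls per week among called genes whose groups overlap in no more than 1 library on either side and whose symbol is not of a predicted gene, the 2 members of each list with the smallest p per week, and the 5 largest rises and falls of each interaction. Members moving against their list are named as well. Alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 5 FPM, rescaling to a total of 1000000, quantile normalization, no trend, library weights, the joint fit, a replicate block, edgeR and DESeq2. Chosen after seeing the data were the fits without single libraries, by sequencing run, without libraries standing apart and with each column as a sample.

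The procedure was tested on simulated data with 200 changed genes. At a 2-fold change 84, 38, 73, 71, 80, 48 and 40% of changed genes were recovered from week 1 to week 48, and at 4-fold 96, 93, 94, 95, 95, 89 and 84%. False calls made up 10, 14.9, 9.73, 13.5, 5.91, 5.52 and 8.15% of calls. Sex and hour of collection are not in the labels and were not used in any fit.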

Results

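Liver RNA was sequenced from C57BL/6J mice, an inbred laboratory strain, that were given either LIDPAD, a diet made to induce non-alcoholic fatty liver disease, or a purified control diet. Feeding began at 8 weeks of age and lasted 1, 4, 8, 12, 16, 32 or 48 weeks, which gave 14 groups. Each duration was tested for transcripts that differed between the diets, and durations were compared for the size of that difference. The labels listed 152 samples. Samples came in blocks of 4 that differed by about the sampling noise of read pairs (chi-square per gene 1.98 to 2.27 within blocks, at least 2.65 between blocks of the same group), and each block was therefore counted as 1 sample, called a library here. This left 38 libraries, 18 from control and 20 from LIDPAD livers: 2 per diet at weeks 1, 4, 8 and 12, 3 per diet at week 16, 4 control and 5 LIDPAD at week 32, and 3 control and 4 LIDPAD at week 48. Nothing in the labels says that the libraries came from separate animals, so all p-values measure the spread between these libraries, which may be technical.

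The deposited unit was FPM (counts divided by a size factor, per 1000000). Whole reads were recovered for 100% of values within 0.02 reads. Median library depth was 29.0 M (1000000 reads). Depth was 24.8 to 53.8 M per library at weeks 1 to 12, 18.7 to 28.7 M at week 16, 10.9 to 32.8 M at week 32 and 18.4 to 34.6 M at week 48. The way reads were divided among the 4 columns of a block separated the libraries into 3 sets, called sequencing runs here: weeks 1 to 12 in run A, week 16 with part of week 32 in run B, and the rest of week 32 with week 48 in run C. Values below are group means ± SD in FPM, and log2 changes ± SE are differences of mean log2(FPM + 0.5), LIDPAD minus control, which understate the change of low genes. All adjusted p-values for genes came from limma, and those for gene lists from camera with a preset correlation. In each week the median and mean change of every called list had the sign of its test. Ranges of a list's adjusted p over alternatives leave out the estimated correlation.

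**Figure D1:**
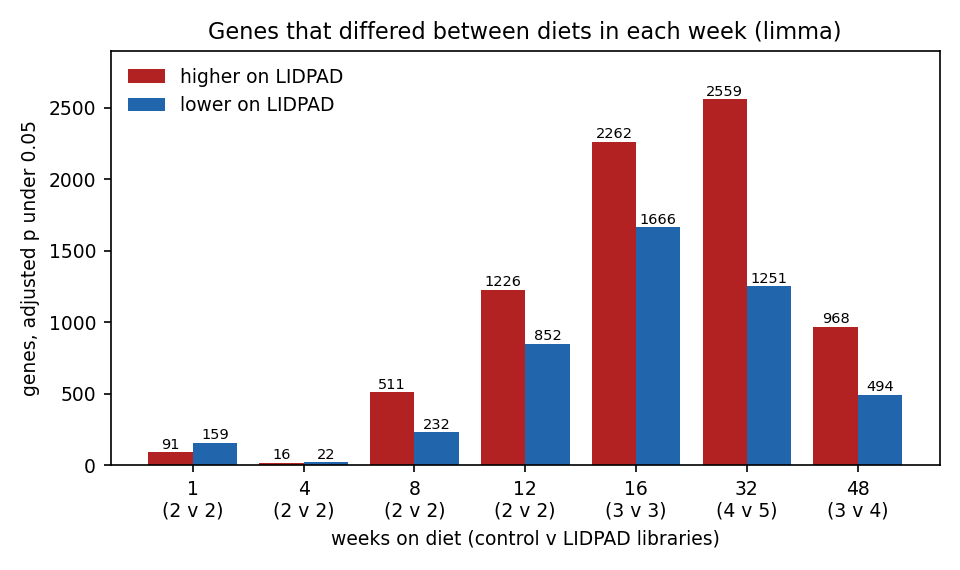
Number of genes with adjusted p under 0.05 (vertical axis) at each feeding duration in weeks (horizontal axis, with the number of control and LIDPAD libraries), red bars for genes higher and blue bars for genes lower on LIDPAD. Counts ran from 16 higher and 22 lower at week 4 to 2262 higher and 1666 lower at week 16, with 2559 higher and 1251 lower at week 32.

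After 1 week on LIDPAD, transcripts for making cholesterol and fatty acids were lower than on the control diet, and transcripts for burning and storing fat were higher (list calls, each lost with an estimated correlation, adjusted p = 0.549 to 0.576). Sqle, which encodes squalene epoxidase of cholesterol synthesis, fell from 52.8 ± 20.4 to 4.18 ± 1.40 FPM (SD, n = 2 libraries per group), with a log2 change -3.49 ± 0.28, adjusted p = 0.00306. Cidec, a lipid droplet protein, rose from 0.793 ± 0.138 to 6.03 ± 3.08 FPM (log2 change 2.25 ± 0.31, adjusted p = 0.0193). The largest rise was in Cfd, the complement protease adipsin secreted by fat cells, from 0.547 ± 0.291 to 24.3 ± 19.7 FPM (log2 change 4.32 ± 0.52, adjusted p = 0.0123). Among the largest falls were Chrna4 (log2 change -4.26 ± 0.42, adjusted p = 0.00541) and Pnpla3 (-3.25 ± 0.49, adjusted p = 0.0262). In total 250 of 12538 tested genes differed, 91 higher and 159 lower.

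For cholesterol synthesis, 22 of 25 tested members fell (24 adjusted over the list alone), with Idi1 (log2 change -3.35 ± 0.14, adjusted p = 0.000425) and Pmvk (log2 change -2.42 ± 0.12, adjusted p = 0.000518) showing the smallest p. The list's median log2 change was -1.90 (adjusted p = 8.96e-40, adjusted p = 0.549 with an estimated correlation). Fatty acid synthesis followed: of 18 tested members 0 rose and 7 fell (1 and 14 adjusted over the list alone), among them Fasn (-2.40, adjusted p = 0.0111), Acss2 (-2.57, adjusted p = 0.00463) and Acacb (-2.48, adjusted p = 0.00541). The list's median log2 change was -1.16 (adjusted p = 9.47e-14, adjusted p = 0.576 with an estimated correlation). Transcripts of fatty acid oxidation, many of them PPAR alpha targets, were higher as a list, although only 3 of 24 tested members rose singly (14 adjusted over the list alone), with Acot2 (log2 change 1.46 ± 0.18, adjusted p = 0.0130) as an example. The list's median log2 change was 0.45 (adjusted p = 1.48e-11, adjusted p = 0.576 with an estimated correlation). Lipid droplet and uptake genes were also higher, including the fatty acid transporter Cd36 (log2 change 1.00 ± 0.11, adjusted p = 0.00814) (median log2 change 0.41, adjusted p = 7.17e-06, adjusted p = 0.549 with an estimated correlation), with 3 of 16 tested members rising (4 adjusted over the list alone). The sterol exporters Abcg5 (1.94, adjusted p = 0.000518) and Abcg8 (1.65, adjusted p = 0.000697) rose with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, which went from 38.1 ± 7.07 to 159 ± 72.0 FPM (log2 change 1.99 ± 0.28, adjusted p = 0.0216). For bile acid synthesis and transport as a whole, of 18 tested members 4 rose and 0 fell (5 and 1 adjusted over the list alone). The bile acid list had a median log2 change of 0.21 (adjusted p = 0.00215, adjusted p = 0.630 with an estimated correlation), a call lost without LIDPAD library 1 (range 1.89e-07 to 0.265).

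Of 16 tested clock genes 6 rose and 2 fell (7 and 4 adjusted over the list alone). Dbp (log2 change 2.72 ± 0.36, adjusted p = 0.0171) was higher, and Npas2 and Cry1, which peak at another hour, were lower. The clock list had a median log2 change of 0.25 (adjusted p = 0.0370, adjusted p = 0.576 with an estimated correlation), a call lost without LIDPAD library 1 or with the stricter filter (range 0.000548 to 0.175). The clock phase, read as log2 Arntl minus log2 Dbp, differed by -4.29 (LIDPAD minus control), beside all groups of this week. Drug-metabolising enzymes rose in part: 3 of 12 tested members rose (5 adjusted over the list alone). Por led with a log2 change 1.76 ± 0.11, adjusted p = 0.00106. The P450 list had a median log2 change of 0.47 (adjusted p = 1.91e-07, adjusted p = 0.576 with an estimated correlation). Markers of Kupffer cells, the resident liver macrophages, were higher as a list while 0 of 10 tested members rose (7 adjusted over the list alone). The list's median log2 change was 0.45 (adjusted p = 2.87e-05, adjusted p = 0.576 with an estimated correlation). Erythroid markers were lower (median log2 change -0.48, adjusted p = 0.00215, adjusted p = 0.576 with an estimated correlation), where 1 of 5 tested members fell (4 adjusted over the list alone). In all, 16 of 27 tested lists were called, 12 higher and 4 lower, and 0 held with an estimated correlation (adjusted p 0.549 to 0.763). The count fell to 33 without control library 1 and 83 without control library 2, and stood at 1123 and 875 without LIDPAD library 1 or 2. Only 14 of the 39 named calls held whichever library was left out, all 39 without either LIDPAD library.

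At week 4 few single genes differed, among them genes of cholesterol synthesis, fat oxidation and the clock. Sqle fell from 43.2 ± 15.6 to 3.25 ± 0.535 FPM (SD, n = 2 libraries per group), with adjusted p = 0.0227. Cyp4a14, a fatty acid hydroxylase induced by PPAR alpha, rose from 31.2 ± 3.27 to 201 ± 0.894 FPM (log2 change 2.67 ± 0.14, adjusted p = 0.00524). Cfd rose from 0.429 ± 0.308 to 102 ± 0.985 FPM (log2 change 6.82 ± 0.24, adjusted p = 0.000797), and Chrna4 fell from 14.8 ± 2.60 to 0.637 ± 0.608 FPM (log2 change -3.85 ± 0.39, adjusted p = 0.0301). Of 13237 tested genes 38 differed, 16 higher and 22 lower.

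Cholesterol synthesis was lower as a list, where 5 of 25 tested members fell (21 adjusted over the list alone), with Idi1 (-3.07, adjusted p = 0.0307) and Lss (-1.61, adjusted p = 0.0301) among those past the threshold. The list's median log2 change was -1.36 (adjusted p = 8.21e-25, adjusted p = 0.630 with an estimated correlation). Lipogenesis was lower too: of 18 tested members 0 rose and 3 fell (1 and 9 adjusted over the list alone), with Acss2 (-2.15, adjusted p = 0.0227) and Pnpla3 (-2.34, adjusted p = 0.0227). The list's median log2 change was -0.63 (adjusted p = 4.95e-07, adjusted p = 0.630 with an estimated correlation). Fat oxidation genes were higher (median log2 change 0.75, adjusted p = 1.33e-15, adjusted p = 0.630 with an estimated correlation), and of 24 tested members 3 rose and 0 fell (17 and 1 adjusted over the list alone). In the lipid droplet list 0 of 17 tested members rose (10 adjusted over the list alone), and Plin4, a droplet coat protein, was just outside the threshold with a log2 change 2.32 ± 0.29, adjusted p = 0.0512. The list's median log2 change was 0.64 (adjusted p = 1.15e-07, adjusted p = 0.630 with an estimated correlation). Clock genes moved both ways, with Per3 (log2 change 2.53 ± 0.27, adjusted p = 0.0307) higher and Arntl (log2 change -1.40 ± 0.14, adjusted p = 0.0301) lower (median log2 change 0.78, adjusted p = 0.00231, adjusted p = 0.630 with an estimated correlation), and of 15 tested members 3 rose and 1 fell (8 and 3 adjusted over the list alone). The clock phase differed by -4.78 (LIDPAD minus control), beside all of these groups.

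Kupffer cell markers were lower, with Marco (log2 change -2.31 ± 0.23, adjusted p = 0.0301), a scavenger receptor, past the threshold (median log2 change -0.55, adjusted p = 1.66e-05, adjusted p = 0.630 with an estimated correlation), and 1 of 11 tested members fell (4 adjusted over the list alone). Recruited macrophage markers were also lower (median log2 change -0.70, adjusted p = 0.000151, adjusted p = 0.630 with an estimated correlation), where 1 of 11 tested members fell (2 adjusted over the list alone), the faller being Fabp5, a fatty acid-binding protein that hepatocytes express too (log2 change -3.07 ± 0.25, adjusted p = 0.0227). Stellate cell markers followed (median log2 change -0.35, adjusted p = 0.00174, adjusted p = 0.630 with an estimated correlation), where 0 of 14 tested members were called (0 adjusted over the list alone). Both of these calls rest on control library 2, for without it neither list was called (ranges 2.05e-10 to 0.847 and 0.000173 to 0.135). The matrix list was lower without control library 1 (adjusted p = 9.60e-12) and higher without control library 2 (0.000131, range 9.60e-12 to 0.494). The control libraries of this week differed from each other more than 4-fold in 88 genes, against 11 for the LIDPAD libraries, and control library 2 held 11.3 FPM of Gpnmb, against 0.132 FPM in control library 1. Counts of genes were 855 without control library 1, where 17 lists were called, and 258 without control library 2. Of 27 tested lists 10 were called, 5 in each direction, and 0 held with an estimated correlation (adjusted p 0.63 to 0.75). Of the 16 named calls 13 held with each library left out in turn, 14 without either LIDPAD library.

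At week 8 transcripts of collagens, recruited macrophages and dividing cells were higher beside those of fat oxidation. These list calls were each lost with an estimated correlation (adjusted p = 0.260 to 0.264). Gpnmb, a marker of lipid-laden macrophages, rose from 0.143 ± 0.00238 to 10.3 ± 3.19 FPM (SD, n = 2 libraries per group), with a log2 change 4.04 ± 0.24, adjusted p = 0.00116. Mmp12, the macrophage elastase, rose from 0.126 ± 0.121 to 11.2 ± 0.763 FPM (log2 change 4.24 ± 0.20, adjusted p = 0.000619). Col3a1, a fibrillar collagen, went from 25.1 ± 2.37 to 87.4 ± 2.23 FPM (log2 change 1.78 ± 0.11, adjusted p = 0.00118), and Cidec from 1.07 ± 0.348 to 24.6 ± 2.26 FPM (log2 change 4.01 ± 0.19, adjusted p = 0.000619). The largest falls were Sqle (log2 change -3.45 ± 0.61, adjusted p = 0.0291), Fabp5 (log2 change -3.11 ± 0.57, adjusted p = 0.0319) and Adgrf1, an adhesion receptor (log2 change -3.09 ± 0.15, adjusted p = 0.000619). Of 13271 tested genes 743 differed, 511 higher and 232 lower, and 869 and 159 with each library rescaled to a total of 1000000, which shifted the median of all genes by 0.10.

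In fat oxidation 17 of 24 tested members rose (21 adjusted over the list alone), led by Cyp4a10 (2.39, adjusted p = 0.00161), Vnn1 (2.36, adjusted p = 0.00161) and Cyp4a14 (3.17, adjusted p = 0.00414). The list's median log2 change was 0.75 (adjusted p = 2.96e-17, adjusted p = 0.264 with an estimated correlation). Fgf21, a hepatocyte hormone, rose as well (log2 change 1.25 ± 0.16, adjusted p = 0.0110). For lipid droplets, of 17 tested members 10 rose and 0 fell (11 and 1 adjusted over the list alone), including lipoprotein lipase, Lpl (log2 change 1.58 ± 0.12, adjusted p = 0.00276). The list's median log2 change was 0.81 (adjusted p = 1.27e-08, adjusted p = 0.264 with an estimated correlation). Cholesterol synthesis stayed lower, with 11 of 25 tested members falling (22 adjusted over the list alone) and Tm7sf2 (log2 change -1.42 ± 0.19, adjusted p = 0.0125) as the smallest p. The list's median log2 change was -1.25 (adjusted p = 2.88e-13, adjusted p = 0.470 with an estimated correlation). In lipogenesis, of 18 tested members 1 rose and 3 fell (1 and 6 adjusted over the list alone), and the member that rose was Srebf1, a transcriptional activator of the pathway (log2 change 0.88 ± 0.16, adjusted p = 0.0284), beside Mlxipl (log2 change -0.53 ± 0.10, adjusted p = 0.0311). The list's median log2 change was -0.88 (adjusted p = 0.000424, adjusted p = 0.611 with an estimated correlation). Glutathione and NRF2 target genes rose: 11 of 14 tested members rose (14 adjusted over the list alone) (median log2 change 0.96, adjusted p = 1.54e-12, adjusted p = 0.260 with an estimated correlation), with Gsta1 going from 1.39 ± 0.794 to 31.2 ± 5.01 FPM, a value that is uncertain because Gsta1 and Gsta2 are close copies. Gluconeogenesis and glucose genes were lower as a list (median log2 change -0.55, adjusted p = 0.000841, adjusted p = 0.444 with an estimated correlation), where of 14 tested members 0 rose and 2 fell (1 and 5 adjusted over the list alone).

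Extracellular matrix genes rose, and of 24 tested members 13 rose and 0 fell (20 and 1 adjusted over the list alone) and Col1a1 (log2 change 2.00 ± 0.14, adjusted p = 0.00161) among them. The matrix list had a median log2 change of 0.76 (adjusted p = 1.54e-12, adjusted p = 0.264 with an estimated correlation). Recruited macrophage markers were higher, and of 13 tested members 10 rose and 1 fell (11 and 1 adjusted over the list alone), the faller again being Fabp5. The recruited macrophage list had a median log2 change of 1.52 (adjusted p = 1.10e-10, adjusted p = 0.260 with an estimated correlation). Trem2, a lipid receptor of these cells, rose from 0.222 ± 0.0508 to 1.66 ± 0.127 FPM (log2 change 1.58 ± 0.22, adjusted p = 0.0138). Kupffer markers also rose in part, for instance Cd5l (log2 change 1.20 ± 0.11, adjusted p = 0.00418), with 4 of 10 tested members rising (6 adjusted over the list alone). The Kupffer cell list had a median log2 change of 0.46 (adjusted p = 0.000200, adjusted p = 0.444 with an estimated correlation). Chemokines were higher (median log2 change 0.81, adjusted p = 9.48e-07, adjusted p = 0.440 with an estimated correlation), and 4 of 11 tested members rose (8 adjusted over the list alone), and Cxcl10 (1.75, adjusted p = 0.00928) and Ccl2 (1.59, adjusted p = 0.0312) were among them. For the cell cycle 7 of 16 tested members rose (11 adjusted over the list alone), such as Mki67 (1.94, adjusted p = 0.00532) and Top2a (1.76, adjusted p = 0.00509). The cell cycle list had a median log2 change of 0.84 (adjusted p = 9.48e-08, adjusted p = 0.264 with an estimated correlation). The clock phase differed by -3.86 (LIDPAD minus control). In total 15 of 27 tested lists were called, 11 higher and 4 lower, and 0 held with an estimated correlation (adjusted p 0.26 to 0.611). Left-out libraries moved the count to 1232 without control library 1, 1665 without control library 2, 116 without LIDPAD library 1 and 82 without LIDPAD library 2, and 19 of the 52 named calls held in every one of these fits.

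At week 12 matrix, macrophage and lipid droplet transcripts were higher, and genes biased towards male liver were lower (list calls, each lost with an estimated correlation, adjusted p = 0.190 to 0.363). Plin4, a coat protein of lipid droplets, rose from 8.17 ± 0.852 to 92.9 ± 7.41 FPM (SD, n = 2 libraries per group), with a log2 change 3.43 ± 0.12, adjusted p = 3.91e-06. Col1a1, a fibrillar collagen chain, rose from 4.80 ± 1.47 to 35.0 ± 6.43 FPM (log2 change 2.76 ± 0.21, adjusted p = 9.30e-05). Hsd3b5, a steroid dehydrogenase that male mouse liver expresses, fell from 209 ± 37.5 to 41.0 ± 2.10 FPM (log2 change -2.33 ± 0.14, adjusted p = 2.33e-05). Among 13631 tested genes 2078 differed, 1226 higher and 852 lower, and 1890 and 396 after rescaling to 1000000, with the median of all genes shifted by 0.19.

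In cholesterol synthesis 24 of 25 tested members fell (24 adjusted over the list alone), with Idi1 (log2 change -3.69 ± 0.14, adjusted p = 3.91e-06) and Msmo1 (log2 change -2.56 ± 0.12, adjusted p = 1.01e-05) leading. The list's median log2 change was -1.94 (adjusted p = 5.52e-31, adjusted p = 0.190 with an estimated correlation). For lipogenesis 12 of 18 tested members fell (12 adjusted over the list alone). The list's median log2 change was -0.76 (adjusted p = 6.37e-08, adjusted p = 0.363 with an estimated correlation). Lipid droplet genes went the other way: 13 of 19 tested members rose (14 adjusted over the list alone), with Cd36 (2.79, adjusted p = 6.03e-06), Cidec (4.44, adjusted p = 6.03e-06) and Cidea (4.08, adjusted p = 1.17e-05). The list's median log2 change was 1.62 (adjusted p = 2.80e-13, adjusted p = 0.190 with an estimated correlation). Oxidation genes stayed higher (median log2 change 0.55, adjusted p = 1.10e-10, adjusted p = 0.190 with an estimated correlation), where 16 of 24 tested members rose (19 adjusted over the list alone). Glutathione genes rose too: 11 of 14 tested members rose (13 adjusted over the list alone). For the NRF2 list the median log2 change was 1.13 (adjusted p = 4.35e-12, adjusted p = 0.190 with an estimated correlation). Drug-metabolising P450 genes were higher (median log2 change 0.43, adjusted p = 0.000267, adjusted p = 0.307 with an estimated correlation), and 5 of 12 tested members rose (7 adjusted over the list alone). The male-biased list fell, and of 16 tested members 0 rose and 9 fell (1 and 10 adjusted over the list alone). For the male-biased list the median log2 change was -0.88 (adjusted p = 8.86e-06, adjusted p = 0.363 with an estimated correlation). In the female-biased list, of 8 tested members 4 rose and 2 fell (6 and 2 adjusted over the list alone), the fallers being Cyp2c40 and Cyp17a1, both steroid or lipid hydroxylases, and Cyp2b9 rose (log2 change 3.15 ± 0.64, adjusted p = 0.0126). With a filter of 5 FPM the direction of this list turned (adjusted p = 0.869), and 9 of 12 alternatives lost its call (range 0.0163 to 0.869). For the female-biased list the median log2 change was 0.83 (adjusted p = 0.0475, adjusted p = 0.363 with an estimated correlation). Clock phase differed by -3.20 (LIDPAD minus control).

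Extracellular matrix rose nearly throughout: of 28 tested members 24 rose and 1 fell (25 and 1 adjusted over the list alone), and the faller was Fn1, fibronectin, which hepatocytes secrete into plasma. For the matrix list the median log2 change was 1.08 (adjusted p = 2.30e-16, adjusted p = 0.307 with an estimated correlation). Recruited macrophage markers followed, where of 13 tested members 11 rose and 1 fell (11 and 1 adjusted over the list alone) and Fabp5 was the faller, with Gpnmb (4.53, adjusted p = 5.84e-05), Mmp12 (4.35, adjusted p = 1.36e-05) and Spp1 (2.00, adjusted p = 0.000112). For the recruited macrophage list the median log2 change was 1.92 (adjusted p = 1.87e-09, adjusted p = 0.363 with an estimated correlation). Chemokines and adhesion molecules rose: 8 of 12 tested members rose (8 adjusted over the list alone). For the chemokine list the median log2 change was 0.85 (adjusted p = 3.17e-05, adjusted p = 0.371 with an estimated correlation). Oncofetal and tumour markers were higher, and of 7 tested members 5 rose and 0 fell (6 and 1 adjusted over the list alone), with H19 (log2 change 2.17 ± 0.23, adjusted p = 0.000648), a fetal non-coding RNA. For the oncofetal list the median log2 change was 1.26 (adjusted p = 0.000181, adjusted p = 0.307 with an estimated correlation). Acute phase proteins split: of 18 tested members 1 rose and 6 fell (1 and 6 adjusted over the list alone), with Saa2 (log2 change -2.79 ± 0.12, adjusted p = 6.03e-06) lower and Orm3 (log2 change 3.99 ± 0.17, adjusted p = 6.03e-06) higher. For the acute phase list the median log2 change was -0.38 (adjusted p = 0.000308, adjusted p = 0.371 with an estimated correlation), a call lost without control library 1 (range 4.04e-13 to 0.0732). Hepatocyte identity genes were lower (median log2 change -0.36, adjusted p = 0.000379, adjusted p = 0.371 with an estimated correlation), and 4 of 16 tested members fell (4 adjusted over the list alone). In total 18 of 28 tested lists were called, 12 higher and 6 lower, and 0 held with an estimated correlation (adjusted p 0.19 to 0.371). Of the 68 named calls 59 held in every fit with a library left out. Counts were 1316 without LIDPAD library 1 and 853 without LIDPAD library 2.

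Week 16, the first with 3 libraries per diet, had calls in every tested matrix gene. Col1a1 rose from 4.97 ± 1.75 to 56.7 ± 7.92 FPM (SD, n = 3 libraries per group), with a log2 change 3.42 ± 0.20, adjusted p = 1.37e-06. Gpnmb rose as well (log2 change 6.04 ± 0.24, adjusted p = 1.28e-07), and Cidec from 1.39 ± 0.131 to 69.7 ± 8.85 FPM (log2 change 5.21 ± 0.13, adjusted p = 6.73e-09). Hsd3b5 fell from 228 ± 56.7 to 7.91 ± 10.3 FPM (log2 change -5.55 ± 0.68, adjusted p = 0.000174), and Sqle fell from 89.1 ± 40.1 to 6.79 ± 2.63 FPM (log2 change -3.55 ± 0.34, adjusted p = 3.63e-05). Of 13914 tested genes 3928 differed, 2262 higher and 1666 lower. After rescaling to 1000000 3958 were higher and 803 lower, with the median of all genes shifted by 0.20.

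In the matrix list, of 28 tested members 27 rose and 1 fell (27 and 1 adjusted over the list alone), Fn1 again being the exception. For the matrix list the median log2 change was 1.54 (adjusted p = 2.31e-20, adjusted p = 0.175 with an estimated correlation). Stellate cell and fibroblast markers rose with them: 10 of 14 tested members rose (11 adjusted over the list alone). For the stellate cell list the median log2 change was 0.85 (adjusted p = 1.41e-06, adjusted p = 0.305 with an estimated correlation). In the recruited macrophage list, of 13 tested members 12 rose and 1 fell (12 and 1 adjusted over the list alone), Fabp5 falling and Mmp12 (5.51, adjusted p = 1.59e-07), Trem2 (3.67, adjusted p = 9.69e-06) and Spp1 (2.88, adjusted p = 5.80e-07) rising. For the recruited macrophage list the median log2 change was 2.88 (adjusted p = 7.45e-12, adjusted p = 0.175 with an estimated correlation). Chemokines rose: 11 of 12 tested members rose (11 adjusted over the list alone). For the chemokine list the median log2 change was 1.28 (adjusted p = 7.28e-08, adjusted p = 0.254 with an estimated correlation). Dividing-cell genes rose as well: of 14 tested members 10 rose and 1 fell (12 and 1 adjusted over the list alone), while Tk1, a thymidine kinase, fell. For the cell cycle list the median log2 change was 1.32 (adjusted p = 1.30e-05, adjusted p = 0.318 with an estimated correlation). Markers of bile duct and progenitor cells were higher (median log2 change 1.20, adjusted p = 0.00249, adjusted p = 0.333 with an estimated correlation), where of 7 tested members 5 rose and 0 fell (6 and 1 adjusted over the list alone), with Krt23 (log2 change 2.62 ± 0.22, adjusted p = 1.90e-05), and the list call was lost with the stricter filter (range 1.23e-06 to 0.119). For oncofetal genes 6 of 7 tested members rose (6 adjusted over the list alone), with Ly6d (5.92, adjusted p = 2.00e-07) and Tspan8 (2.55, adjusted p = 2.17e-05). For the oncofetal list the median log2 change was 2.07 (adjusted p = 4.77e-05, adjusted p = 0.254 with an estimated correlation).

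Among lipid genes 24 of 25 tested members fell (24 adjusted over the list alone) in cholesterol synthesis. For the cholesterol synthesis list the median log2 change was -1.94 (adjusted p = 1.81e-19, adjusted p = 0.254 with an estimated correlation). In lipogenesis, of 18 tested members 1 rose and 10 fell (1 and 12 adjusted over the list alone), and the one that rose was Scd1, the stearoyl-CoA desaturase, from 4899 ± 779 to 13547 ± 4827 FPM. For the lipogenesis list the median log2 change was -0.58 (adjusted p = 0.000419, adjusted p = 0.356 with an estimated correlation). Lipid droplet genes rose: 14 of 19 tested members rose (16 adjusted over the list alone). For the lipid droplet list the median log2 change was 1.74 (adjusted p = 7.50e-12, adjusted p = 0.116 with an estimated correlation). In bile acid synthesis and transport, of 18 tested members 2 rose and 7 fell (3 and 9 adjusted over the list alone), with the uptake carrier Slc10a1 (log2 change -1.73 ± 0.16, adjusted p = 3.53e-05) lower and the phospholipid exporter Abcb4 higher (from 167 ± 18.7 to 408 ± 8.52 FPM, adjusted p = 1.30e-05). For the bile acid list the median log2 change was -0.29 (adjusted p = 0.0220, adjusted p = 0.513 with an estimated correlation), a call lost with the stricter filter, after quantile normalization and without control library 1 (range 0.00112 to 0.301). Male-biased genes fell: of 15 tested members 1 rose and 10 fell (1 and 10 adjusted over the list alone), for instance Serpina1e (log2 change -2.27 ± 0.22, adjusted p = 3.99e-05), while the male-biased Mup20 rose with a log2 change 0.78 ± 0.19, adjusted p = 0.00999 and is uncertain, as the Mup genes are near-identical copies. The male-biased list as a whole was lower (adjusted p = 1.25e-05, adjusted p = 0.356 with an estimated correlation). Hepatocyte identity genes were lower (median log2 change -0.35, adjusted p = 0.000161, adjusted p = 0.175 with an estimated correlation), and 7 of 16 tested members fell (8 adjusted over the list alone), such as Cps1 (log2 change -1.15 ± 0.14, adjusted p = 0.000195), the first enzyme of the urea cycle. Quantile normalization ended this list call (range 2.85e-07 to 0.0646). The clock phase differed by -0.81 between diets. All told 18 of 28 tested lists were called, 11 higher and 7 lower, and 0 held with an estimated correlation (adjusted p 0.116 to 0.572). Of the 72 named calls 68 held with each library left out in turn.

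At week 32 macrophage and matrix transcripts were above control, and male-biased and cholesterol synthesis transcripts below (list calls, each lost with an estimated correlation, adjusted p = 0.180 to 0.194). Gpnmb rose from 0.167 ± 0.178 to 109 ± 141 FPM (SD, n = 4 and 5 libraries), with a log2 change 6.68 ± 0.62, adjusted p = 6.22e-05. Lcn2, the iron-binding acute phase protein lipocalin, rose from 1.45 ± 0.863 to 204 ± 242 FPM (log2 change 6.22 ± 0.57, adjusted p = 6.22e-05). Ubd rose from 0.0712 ± 0.0924 to 30.4 ± 17.3 FPM (log2 change 5.60 ± 0.34, adjusted p = 8.51e-06). Slco1a1, an organic anion transporter, fell from 639 ± 116 to 16.7 ± 3.77 FPM (log2 change -5.23 ± 0.17, adjusted p = 7.73e-08), and Hsd3b5 fell from 132 ± 48.6 to 0.573 ± 0.768 FPM (log2 change -7.11 ± 0.41, adjusted p = 7.84e-06). Of 14187 tested genes 3810 differed, 2559 higher and 1251 lower.

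Recruited macrophage markers rose almost without exception: 12 of 13 tested members rose (12 adjusted over the list alone), with Trem2 (4.54, adjusted p = 3.11e-05), Itgax (4.31, adjusted p = 3.91e-05) and Spp1 (3.85, adjusted p = 0.000263). Recruited macrophage genes had a median log2 change of 3.59 (adjusted p = 1.82e-09, adjusted p = 0.180 with an estimated correlation). In the matrix list, of 28 tested members 26 rose and 1 fell (26 and 1 adjusted over the list alone), Fn1 falling, and Col5a2 (2.95, adjusted p = 5.14e-05), Lum (2.43, adjusted p = 5.80e-05) and Col1a1 (3.41, adjusted p = 0.000364) leading. Matrix genes had a median log2 change of 1.92 (adjusted p = 3.31e-13, adjusted p = 0.180 with an estimated correlation). Stellate cell markers rose in part: of 14 tested members 7 rose and 1 fell (9 and 1 adjusted over the list alone), with Pdgfrb (log2 change 1.54 ± 0.23, adjusted p = 0.000830) higher and Ecm1, a matrix protein that restrains TGF beta, lower. Stellate cell genes had a median log2 change of 0.68 (adjusted p = 0.00817, adjusted p = 0.222 with an estimated correlation). Among Kupffer markers, which were not called as a list (median log2 change 0.72, adjusted p = 0.283), Cd163 fell from 15.6 ± 3.50 to 1.12 ± 0.988 FPM (log2 change -3.45 ± 0.32, adjusted p = 6.64e-05) while C1qb (log2 change 2.60 ± 0.32, adjusted p = 0.000271) rose. Interferon-response genes were higher: 17 of 23 tested members rose (17 adjusted over the list alone). Interferon genes had a median log2 change of 0.84 (adjusted p = 9.89e-07, adjusted p = 0.209 with an estimated correlation). For B cells 3 of 7 tested members rose (7 adjusted over the list alone), led by Cd22 (log2 change 2.37 ± 0.40, adjusted p = 0.00160). B cell genes had a median log2 change of 1.46 (adjusted p = 0.00654, adjusted p = 0.361 with an estimated correlation), a call lost without LIDPAD library 5 (range 0.000404 to 0.0524). Library 1 had a median log2 level of 2.79 over control for this list, against 0.742 to 1.05 in the other 4, and the call held without it. T and NK cell markers were not called as a list (median log2 change 1.15, adjusted p = 0.0616). Bile duct and progenitor markers rose: 7 of 9 tested members rose (8 adjusted over the list alone), including Krt19 (log2 change 2.35 ± 0.68, adjusted p = 0.0245), a bile duct keratin. Bile duct genes had a median log2 change of 2.41 (adjusted p = 0.000178, adjusted p = 0.287 with an estimated correlation). In the oncofetal list 6 of 7 tested members rose (6 adjusted over the list alone), with Tspan8 (log2 change 3.72 ± 0.40, adjusted p = 0.000152), while Afp, the fetal albumin relative, had a log2 change -0.020 ± 0.32, adjusted p = 0.973. Oncofetal genes had a median log2 change of 3.03 (adjusted p = 0.000239, adjusted p = 0.186 with an estimated correlation).

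Male-biased genes fell: 10 of 15 tested members fell (10 adjusted over the list alone) (median log2 change -2.24, adjusted p = 1.82e-09, adjusted p = 0.180 with an estimated correlation), and in the female-biased list 5 of 8 tested members rose (5 adjusted over the list alone). Female-biased genes had a median log2 change of 2.31 (adjusted p = 0.0340, adjusted p = 0.361 with an estimated correlation), a call lost in 5 of 22 alternatives (range 0.00175 to 0.2355). Cholesterol synthesis remained lower: 24 of 25 tested members fell (25 adjusted over the list alone), with Fdft1 (-1.69, adjusted p = 0.000697), Mvd (-2.08, adjusted p = 0.000788) and Sqle (-2.84, adjusted p = 0.00534). Cholesterol synthesis genes had a median log2 change of -1.69 (adjusted p = 4.81e-14, adjusted p = 0.194 with an estimated correlation). The lipogenesis list was lower too: of 18 tested members 0 rose and 12 fell (1 and 12 adjusted over the list alone). Lipogenesis genes had a median log2 change of -0.93 (adjusted p = 4.78e-06, adjusted p = 0.293 with an estimated correlation), a call lost in run C alone (range 9.91e-11 to 0.0898). Fat oxidation was not called (median log2 change -0.10, adjusted p = 0.381), but was lower in run B alone (0.0307) and higher in run C alone (0.0483, range 0.0307 to 0.804). Lipid droplet genes were higher: of 18 tested members 8 rose and 1 fell (8 and 1 adjusted over the list alone), with Lpl (log2 change 4.30 ± 0.38, adjusted p = 5.80e-05) rising and Dgat2, an enzyme of triglyceride synthesis, falling. Lipid droplet genes had a median log2 change of 0.69 (adjusted p = 0.0340, adjusted p = 0.361 with an estimated correlation). This call was lost in 9 of 22 alternatives (range 4.67e-18 to 0.169), among them the sequencing run as a covariate (0.0627), run B alone (0.169) and rescaling. Genes of the endoplasmic reticulum stress response fell: 12 of 19 tested members fell (14 adjusted over the list alone). Stress response genes had a median log2 change of -0.80 (adjusted p = 5.66e-07, adjusted p = 0.194 with an estimated correlation). Bile acid genes were lower (median log2 change -0.66, adjusted p = 0.000672, adjusted p = 0.194 with an estimated correlation), and of 18 tested members 3 rose and 8 fell (3 and 10 adjusted over the list alone), the risers being Abcg5, Abcg8 and Abcb4, exporters of sterols and phospholipid. Quantile normalization ended this call (range 1.44e-11 to 0.121) and that of the next list (range 4.02e-07 to 0.347). For hepatocyte identity 7 of 16 tested members fell (7 adjusted over the list alone). Hnf4a was among them (log2 change -0.98 ± 0.14, adjusted p = 0.000544). Hepatocyte identity genes had a median log2 change of -0.65 (adjusted p = 5.87e-05, adjusted p = 0.180 with an estimated correlation). Clock phase differed by -1.01.

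Week 32 spanned sequencing runs B and C. Within run B, with 3 libraries per diet, 3261 genes differed, and within run C, with 1 control and 2 LIDPAD libraries, 6904. The LIDPAD libraries of run C were the closest pair of the data set (chi-square per gene 2.65), so calls in run C rest on a small spread and 1 control. Log2 changes in runs B and C were 6.92 and 6.41 for Gpnmb and -6.90 and -7.67 for Hsd3b5, but sizes lay further apart for others, such as Lcn2 (7.14 and 4.46), Spp1 (4.60 and 1.96), Plin4 (1.71 and 4.01), Elovl3 (-5.92 and -2.15) and Acly (-2.21 and -0.659). The sign differed for Fasn (-2.07 and 0.20) and Cry1 (-1.04 and 0.026). Cholesterol synthesis had a median log2 change of -1.68 in run B and -1.39 in run C. LIDPAD libraries 1 and 2 lay more than 4-fold from the rest of their group in 192 and 122 genes, and leaving out both gave 3541 genes. After rescaling to 1000000 4070 genes were higher and 362 lower, after quantile normalization 1807 and 1756, and the median of all genes shifted by 0.33 and -0.10. Of the 70 named calls 55 held with each library left out in turn. In total 20 of 30 tested lists were called, 12 higher and 8 lower, and 0 held with an estimated correlation (adjusted p 0.18 to 0.58).

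After 48 weeks macrophage, matrix and lymphocyte transcripts were higher and cholesterol synthesis transcripts lower (list calls, each lost with an estimated correlation, adjusted p = 0.282 to 0.388). Gpnmb rose from 3.52 ± 5.55 to 70.0 ± 14.9 FPM (SD, n = 3 and 4 libraries), with a log2 change 5.20 ± 0.83, adjusted p = 0.0151. Plin4 rose from 13.0 ± 6.28 to 116 ± 11.6 FPM (log2 change 3.23 ± 0.31, adjusted p = 0.00273), and Col1a1 rose from 14.5 ± 20.5 to 66.6 ± 7.77 FPM (log2 change 3.21 ± 0.80, adjusted p = 0.0445). Without control library 3 the log2 changes of Gpnmb and Col1a1 were 6.43 and 4.42, and without any 1 of the other 6 libraries Col1a1 was not called (adjusted p = 0.106 to 0.144). Sqle fell from 72.9 ± 5.73 to 7.12 ± 3.08 FPM (log2 change -3.34 ± 0.25, adjusted p = 0.000994). Marco fell from 15.9 ± 15.8 to 0.994 ± 0.328 FPM (log2 change -2.98 ± 0.62, adjusted p = 0.0253). Hsd3b5 had a log2 change -4.94 ± 1.53, adjusted p = 0.0799. Controls 1 to 3 held 186, 179 and 1.02 FPM, against 0.467 to 1.24 on LIDPAD. Of 14807 tested genes 1462 differed, 968 higher and 494 lower, and 2879 and 190 after rescaling to 1000000, with the median of all genes shifted by 0.28.

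Recruited macrophage markers rose: of 14 tested members 9 rose and 0 fell (12 and 1 adjusted over the list alone), such as Trem2 (2.83, adjusted p = 0.00844) and Mmp12 (3.84, adjusted p = 0.0231). Recruited macrophage genes had a median log2 change of 2.33 (adjusted p = 3.22e-06, adjusted p = 0.388 with an estimated correlation). In the matrix list, of 28 tested members 15 rose and 0 fell (24 and 1 adjusted over the list alone), with Dcn (1.09, adjusted p = 0.00113), Col6a1 (1.76, adjusted p = 0.0177) and Timp1 (1.78, adjusted p = 0.0186). Matrix genes had a median log2 change of 1.60 (adjusted p = 4.16e-11, adjusted p = 0.388 with an estimated correlation). Stellate cell markers rose too: 9 of 14 tested members rose (10 adjusted over the list alone). Stellate cell genes had a median log2 change of 0.78 (adjusted p = 1.17e-06, adjusted p = 0.282 with an estimated correlation). Lymphocyte markers were higher: for B and plasma cells 5 of 9 tested members rose (8 adjusted over the list alone). B cell genes had a median log2 change of 1.16 (adjusted p = 6.79e-06, adjusted p = 0.388 with an estimated correlation). For T and NK cells 3 of 6 tested members rose (4 adjusted over the list alone), Cd8a (0.94, adjusted p = 0.0278) among them. T and NK cell genes had a median log2 change of 0.91 (adjusted p = 0.00120, adjusted p = 0.282 with an estimated correlation). Neutrophil markers were called as higher on 3 tested members, of which 1 rose, Csf3r (2 adjusted over the list alone, median log2 change 0.96, adjusted p = 0.0319, adjusted p = 0.388 with an estimated correlation), a call lost after rescaling or quantile normalization and without control library 1 or 3 (range 4.53e-06 to 0.146). Bile duct markers were higher (median log2 change 0.99, adjusted p = 0.0149, adjusted p = 0.650 with an estimated correlation), where 1 of 11 tested members rose (1 adjusted over the list alone), a call lost with the stricter filter, after rescaling and without control library 1 or 2 (range 2.495e-06 to 0.353).

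Cholesterol synthesis was lower: 20 of 25 tested members fell (23 adjusted over the list alone). Cholesterol synthesis genes had a median log2 change of -1.28 (adjusted p = 8.60e-25, adjusted p = 0.282 with an estimated correlation). The lipogenesis list was lower, where 1 of 18 tested members fell, Slc25a1, the mitochondrial citrate carrier (0 adjusted over the list alone, median log2 change -0.43, adjusted p = 0.0173, adjusted p = 0.680 with an estimated correlation), a call lost with the stricter filter, after quantile normalization and without control library 1 (range 3.03e-06 to 0.708). Lipid droplet genes rose: 6 of 19 tested members rose (10 adjusted over the list alone), including Pparg (log2 change 1.23 ± 0.19, adjusted p = 0.0135), a driver of fat storage. Lipid droplet genes had a median log2 change of 0.70 (adjusted p = 2.41e-05, adjusted p = 0.388 with an estimated correlation). In fat oxidation, of 24 tested members 4 rose and 1 fell (7 and 2 adjusted over the list alone), with Acaa1b (log2 change 0.96 ± 0.16, adjusted p = 0.0169) higher and Fgf21 (log2 change -1.91 ± 0.39, adjusted p = 0.0241) lower. Fat oxidation genes had a median log2 change of 0.14 (adjusted p = 0.0455, adjusted p = 0.388 with an estimated correlation), a call lost without control library 1 or 3 or LIDPAD library 2 or 4 (range 1.26e-05 to 0.104). The stress response list was lower: of 19 tested members 0 rose and 6 fell (1 and 14 adjusted over the list alone). Fallers included Atf4 (-0.87, adjusted p = 0.00999) and Asns (-2.09, adjusted p = 0.0156). Stress response genes had a median log2 change of -0.46 (adjusted p = 3.07e-07, adjusted p = 0.388 with an estimated correlation). Mitochondrially encoded transcripts were lower (median log2 change -0.41, adjusted p = 4.87e-05, adjusted p = 0.388 with an estimated correlation), where 2 of 13 tested members fell (7 adjusted over the list alone). After quantile normalization the direction of this list turned (adjusted p = 0.902, range 2.68e-09 to 0.902). Male-biased genes were lower: 4 of 15 tested members fell (10 adjusted over the list alone). Male-biased genes had a median log2 change of -1.12 (adjusted p = 5.65e-06, adjusted p = 0.388 with an estimated correlation). Sinusoidal endothelial markers were called in none of the 7 weeks, here with a median log2 change of 0.089 and adjusted p = 0.901. The clock phase differed by -2.41 (LIDPAD minus control).

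Control library 3 of week 48 lay more than 4-fold from the other controls in 420 genes, and without it 5714 genes differed and all 54 named and called genes kept their call. Leaving out another library lowered the count to 361 and 488 for control libraries 1 and 2, and to 270, 163, 134 and 177 for LIDPAD libraries 1 to 4, and 13 of the 54 named calls held in every such fit. Of 30 tested lists 18 were called, 10 higher and 8 lower, and 0 held with an estimated correlation (adjusted p 0.282 to 0.68). Adipocyte markers were too few to test in each week, with 2 members, Cfd and Adrb3, above the filter, and 0 pancreatic acinar markers passed it.

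**Figure D2:**
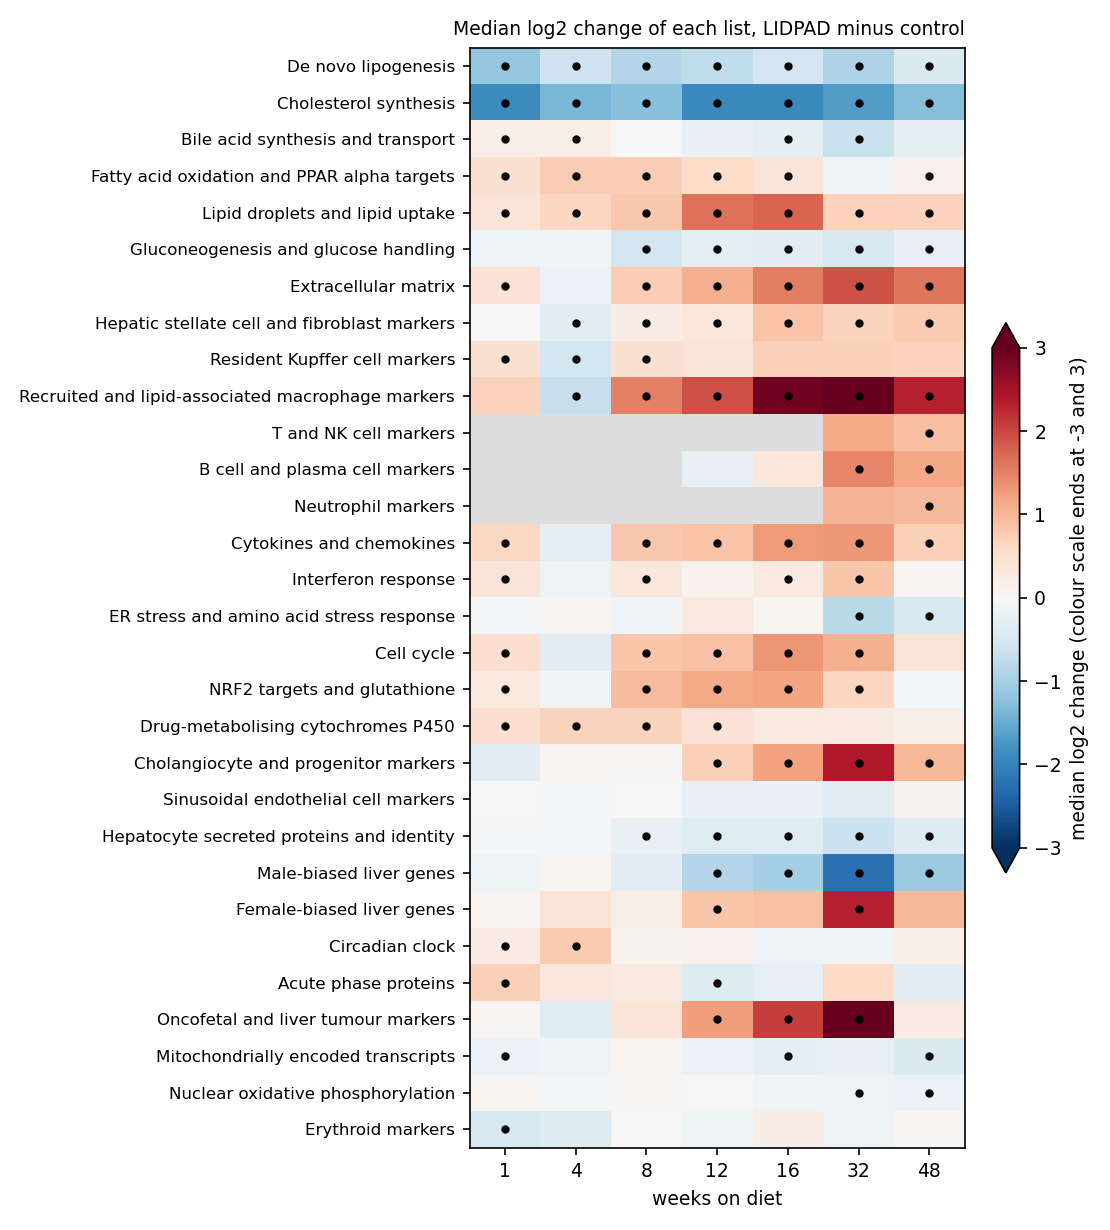
Median log2 change (colour, LIDPAD minus control) of the tested members of each gene list (vertical axis) by weeks on diet (horizontal axis), with a dot where camera with a preset correlation gave an adjusted p under 0.05 and grey where fewer than 3 members were tested. Cholesterol synthesis has medians from -1.94 to -1.25 and a dot in every week, recruited macrophage markers reach 3.59 at week 32, and 0 of the dots held with an estimated correlation.

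Set against each other, the weeks shared a small core of genes. Higher in all 7 weeks were Cfd, with log2 changes of 4.32, 6.82, 4.98, 5.41, 4.65, 3.02 and 3.05 from week 1 to week 48, and Adam11, a member of a membrane protease family (2.26 at week 1 and 1.85 at week 48). Lower in all 7 weeks were Sqle, Cyp51 and Idi1 of cholesterol synthesis, the retinol dehydrogenase Rdh11 and the predicted gene Gm13502, the last named after its values were seen. Sqle had its smallest fall at week 32 (-2.84) and its largest at week 12 (-3.65). Independent lists would have shared 4.47e-07 genes higher and 1.45e-07 lower among the 12330 genes tested in every week. In at least 4 weeks 426 genes were higher and 198 lower, and 71 genes were called in both directions in different weeks. The weekly comparisons had no control library in common. Weeks 12 and 16 shared 832 genes higher and 591 lower (147.9 and 101.6 for independent lists), weeks 16 and 32 shared 1054 and 623 (270.1 and 157.2), and weeks 1 and 48 shared 15 and 46 (5.24 and 5.73). The count of genes called in all 7 weeks rose to 13 and 17 without week 4 control library 1 or 2, and fell to 2 and 0 without week 8 LIDPAD library 1 or 2.

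Whether the diet difference varied between weeks was tested in a joint limma fit of all 14 groups. Spp1, the matrix protein osteopontin, had log2 changes of 0.10, -0.51, 0.94, 2.00, 2.88, 3.85 and 2.29 in the weekly fits (adjusted p = 0.00613 for any difference between weeks). Hsd3b5 went from -0.28 at week 1 to -7.11 at week 32 (adjusted p = 0.00606), and Lcn2 had -0.088 at week 12 and 6.22 at week 32 (adjusted p = 0.0301). Much of the Lcn2 change lay in the controls, which held 30.7 and 136 FPM at week 12 and 0.782 to 2.69 FPM at week 32. LIDPAD libraries held 48.7 and 76.1 FPM and 65.6 to 634 FPM in those weeks. For Sqle, lower in every week, the same test gave adjusted p = 0.979, and for Cd36, Col1a1 and Cidec 0.0531, 0.183 and 0.271, none of which shows an unchanged difference. In total 1328 of 12330 genes had a diet difference that varied between weeks. Hour and run were not separated from duration, and the clock phase difference ran from -4.78 (week 4) to -0.81 (week 16). Singled out after the values were seen, the smallest p belonged to Cc2d2a, Trp53inp2 and Cyp2f2, a cytochrome P450.

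Single contrasts, each between different runs, found few genes. Cyp2f2 was the 1 gene whose diet difference at week 48 differed from that at week 1, lower by a log2 difference of -2.54 ± 0.40 (SE, adjusted p = 0.00837). Between weeks 48 and 16 the difference changed for 3 genes, among them Cyp2f2 (-2.08 ± 0.36, adjusted p = 0.0155). The others were Alg12 (-1.45 ± 0.25, adjusted p = 0.0155) and Sec22b (-0.83 ± 0.16, adjusted p = 0.0431). Between weeks 16 and 1 limma called 0 genes, with 1166 at an unadjusted p under 0.05. The contrast of weeks 48 and 1 gave 295 genes without week 48 control library 3 and 0 without week 1 control library 1 or 2 or LIDPAD library 1. That of weeks 48 and 16 ranged from 0 to 15, and that of weeks 16 and 1 gave 49 without week 48 control library 3. The F test gave 2052 genes without that library, 787 without week 4 control library 2 and 748 without week 4 LIDPAD library 2.

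**Figure D3:**
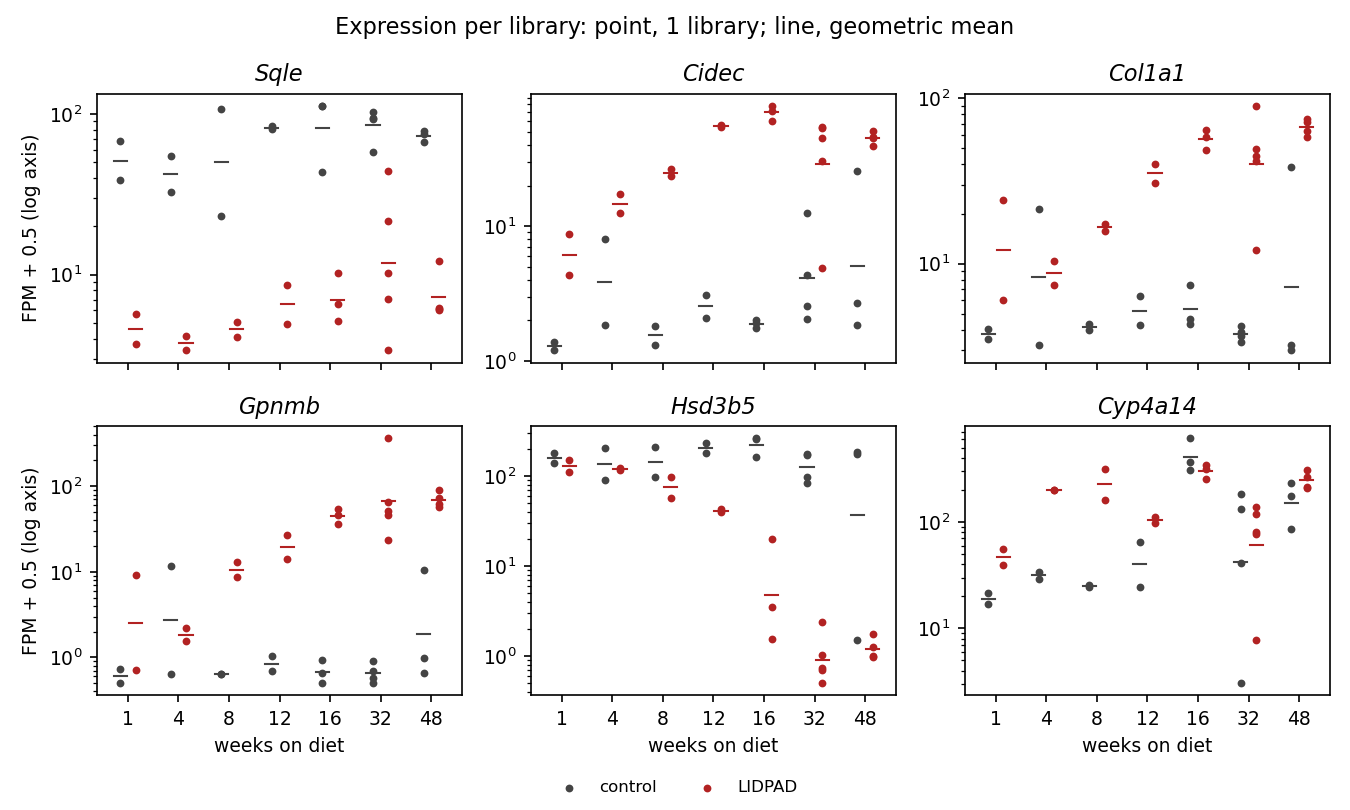
Expression of 6 index genes (vertical axes, FPM + 0.5, log scale) by weeks on diet (horizontal axis), 1 point per library and a line at the geometric mean of each group, grey for control and red for LIDPAD. Sqle lies below every control library of its week in each LIDPAD library, and Gpnmb, Cidec and Col1a1 of week 48 control library 3 lie between the other control libraries and the LIDPAD libraries of that week.

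The plotted genes lie, in the GENCODE annotation of mouse assembly GRCm38, as follows: Sqle (ENSMUSG00000022351) on chromosome 15 from 59315077 to 59331192, Cidec (ENSMUSG00000030278) on chromosome 6 from 113424634 to 113435760 and Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042. Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929, Hsd3b5 (ENSMUSG00000038092) on chromosome 3 from 98618634 to 98630252 and Cyp4a14 (ENSMUSG00000028715) on chromosome 4 from 115486200 to 115496142 complete the set. The annotation version and strand setting used for counting are not stated, so reads of overlapping and antisense genes cannot be assigned.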

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

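Tests of a wrong label, a mixture, tumour tissue, a female liver, shallower sequencing and the albumin level were chosen after the results were seen. In week 48 LIDPAD livers, library 3 held 2467 FPM of Fasn (1183 to 1266 in the others) and library 4 held 11.7 FPM of Sqle (5.48 to 5.67). In week 32 LIDPAD livers, library 1 held 4.37 FPM of Cidec (29.7 to 54.1 in the others) and 0.716 FPM of Clec4f (33.8 to 76.0). Library 2 held 7.37 FPM of Cyp4a14 (77.4 to 137.1), and library 3 held 18.7 FPM of Fgf21 (3.74 to 5.91). These 6 came from 102 groups tested for a library far from the rest, where chance gives about 1 in 20, or 5.1. The diet difference varied between weeks for 1328 genes, between weeks 48 and 1 for 1 and between weeks 48 and 16 for 3. Among index genes it varied for Spp1 (adjusted p = 0.00613), Lcn2 (0.0301) and Hsd3b5 (0.00606), by limma. Hour and run were not separated from duration.

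Control library 3 of week 48 stood apart from the other controls. A LIDPAD library labelled control is argued against by the cholesterol synthesis genes, at a median position of 0.247, where 0 is control and 1 LIDPAD, although other lists lay near or past the LIDPAD level, such as lipid droplets (0.979), male-biased (1.02), female-biased (1.11), cytokine (1.05), bile duct (0.991) and bile acid (1.35) genes. A mixture of the sequenced livers is argued against by 35 genes over 4-fold outside the range of the other 6 libraries (next library 7). One with other LIDPAD RNA stays open. Liver tumour tissue in the sample also stays open. The oncofetal list had a median log2 level of 3.62 over controls 1 and 2, against at most 1.60 in any other library. The cell cycle list had 2.39, against 1.46. Afp did not stand out (6.10 FPM, 3.43 to 7.11 in the other 6 libraries), and no other biological explanation was tested.

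Cholesterol synthesis transcripts were lower on LIDPAD in every week. A different hour of collection stays open in every week, as the clock-phase covariate (weakest median log2 change -1.28) drew only on spread within groups. Phase differed by -0.81 and -1.01 at weeks 16 and 32 (medians -1.94 and -1.69), but similar phase need not mean similar hour. The sequencing run is argued against by a median of -1.68 in run B of week 32, with 3 libraries per diet, and -1.39 in run C, with 1 control. A diet effect may remain, as a hypothesis, and the composition of the diets was not tested.

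LIDPAD library 1 of week 32 stood apart from its group. RNA of blood or lymphoid tissue could account for part, as T and NK cell markers had a median log2 level of 1.33 over control, against at most 1.12 in the other LIDPAD libraries, with 676 FPM of Igkc and 1440 FPM of Ighm. Dilution by such RNA is argued against for Clec4f and Clec4g (0.716 and 0 FPM), because Alb stood at 92258 FPM, against at most 29513 in the others. A female liver is argued against by 68.1 FPM of Ddx3y, and shallower sequencing by 207 genes more than 4-fold from the rest after thinning, against 125. Library 1 also held 1.59% of its reads in Rn7sk, against 0.511 to 1.12% in the other LIDPAD libraries and 0.450 to 0.595% in controls, and its RNA quality was not tested. What lowered these markers stays open, and no other biological explanation was tested.

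Other splits of the same libraries gave the following. At week 16 the real split was the highest, 1 of 10 for genes (3928, highest other 0) and 1 of 10 for lists (18, highest other 16), too few splits for a share under 0.05. At week 32, 1 of 100 splits gave as many genes (3810, highest other 2135, a split that kept LIDPAD libraries 1, 2, 3 and 5 together). This is a share under 0.05 that makes chance unlikely but does not exclude it. As many lists came in 4 of 100 (20, highest other 21). That share is under 0.05, but 2 other splits called more lists than the real one and the splits took no account of the runs, so the number of lists does not mark the diet grouping; run B alone gave 20 lists. At week 48, 1 of 35 gave as many genes (1462, highest other 0), the smallest share that 35 splits can give. Chance is thus unlikely for the genes but not excluded. As many lists came in 5 of 35 (18, highest other 20), a share that leaves chance open. For the contrast of weeks 48 and 16, 1 of 100 exchanges gave as many genes (3, highest other 0).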

How the results depend on the processing

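Chosen after the results were seen were the tests without single libraries, by run, without libraries standing apart, without week 4 and with each column as a sample. Of 607 values of named genes 375 were called, and the alternatives fixed beforehand gave 7051 values: 6394 kept direction and side of the threshold, 425 lost it, 176 gained it, 56 uncalled ones changed sign and 0 called ones reversed. Those chosen later gave 4465, of which 3616 kept both, 424 lost the threshold, 337 gained it, 78 uncalled ones changed sign and 10 changed sign with a call in 1 of the 2 fits, of which Fasn and Cry1 at week 32 were called in the main fit. With the replicate block 383 genes were called at week 1, 368 at week 4, 15 at week 48 and 4 in all 7 weeks. Correlations of same-numbered libraries ran from -0.12 to 0.12, so the numbers do not pair the libraries. Without the variance trend 63, 4 and 471 genes were called at weeks 1, 4 and 8. The joint fit called 12, 34, 235 and 2302 at weeks 1, 8, 12 and 16. DESeq2 called 480, 308, 1264 and 2424 at weeks 1, 4, 8 and 48. Without a filter the counts were 106, 478 and 1344 at weeks 4, 8 and 12, 2 and 5 for week 48 against weeks 1 and 16, and 11 in all 7 weeks. Rescaling to 1000000 gave 25 and 3069 at weeks 4 and 48 and 0 for both contrasts of week 48. Library weights gave 70 and 4670 at weeks 4 and 48, and the stricter filter 729 genes in the F test, where fewer genes were tested. After quantile normalization the direction turned at week 32 for the mitochondrially encoded (adjusted p = 0.00870) and oxidative phosphorylation (adjusted p = 0.577) lists. Lists called by camera with an estimated correlation were 0 in each of the 7 weeks, and in the other alternatives 7, 3, 2, 4, 6, 10 and 9 of the called lists from week 1 to week 48 lost the call at least once. For all other counts these settings stayed within 1.5 times, and the cause of the changes was not tested.

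With each column as its own sample, which counts parts of a library as replicates, 2839, 2925, 4857, 5335, 6530, 7342 and 5729 genes were called from week 1 to week 48. The F test then gave 8025, the contrasts of weeks 16 and 1, 48 and 1, and 48 and 16 gave 2304, 2182 and 1936, and 240 genes were called in all 7 weeks. Run C alone gave 6904 genes at week 32, and reversed Clec4f (0.74), Cry1 (0.026), Cyp7a1 (-0.30) and Fasn (0.20). Leaving out the 3 libraries standing apart, week 4 control 2, week 32 LIDPAD 1 and week 48 control 3, gave 214, 632 and 13 genes for the contrasts and 35 in all 7 weeks, and leaving out week 4 gave 21.

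Leaving out single libraries gave 33 to 1123 genes at week 1, 39 to 855 at week 4 (12 to 17 lists), 82 to 1665 at week 8, 853 to 3104 at week 12 and 134 to 5714 at week 48, with each library that moved a count named in the report. A group left with 1 library is assumed to vary like the other. Ranges were 748 to 2052 for the F test, 0 to 49 for week 16 against 1, 0 to 295 for week 48 against 1, 0 to 15 for week 48 against 16 and 0 to 17 in all 7 weeks. For week 48 against 1 there were 0 genes without week 1 control library 1 or 2 or LIDPAD library 1, 2 without week 12 control library 1 or 2, week 32 control library 3 or week 32 LIDPAD library 1, 3 without week 32 LIDPAD library 2 and 295 without week 48 control library 3. For week 48 against 16 there were 15 genes without week 16 control library 1, 0 without week 16 control library 2 or 3, week 16 LIDPAD library 2 or 3 or week 48 LIDPAD library 1, 9 and 7 without week 32 LIDPAD libraries 1 and 2, and 7 and 6 without week 48 control libraries 2 and 3. Log2 changes at week 4 without control library 1 and without control library 2 were -1.28 and 1.45 for Col1a1, -1.01 and 0.92 for Col3a1, -1.14 and 1.88 for Krt23, and -1.39 and 2.36 for Lcn2. At week 8 those of Saa1 were 2.51 and -0.98, and at week 12 those of Lcn2 0.98 and -1.16, so each of these directions rests on 1 control library. Depth limits the low genes most at week 32, where a library held 10.9 M reads.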

Other observations

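All gene families here were chosen after the results were seen, 24 in number with 166 tests by camera, of which 96 were called and 0 held with an estimated correlation. MHC class II genes, which present antigen to helper T cells, were higher at week 1 (median log2 change 0.544, adjusted p = 0.000942, 0 of 5 tested members called) and from week 8 on. Of their tested members 4 of 5 rose at week 8 (median log2 change 1.36, adjusted p = 1.27e-05), 5 of 6 at week 12 (1.45), 6 of 6 at week 16 (2.49), 7 of 7 at week 32 (2.80) and 6 of 7 at week 48 (1.82, adjusted p = 9.96e-05), with adjusted p = 0.455 with an estimated correlation at each, and the direction held under both other scalings. Major urinary proteins, pheromone carriers made by male liver from near-identical genes, fell at week 32 in 18 of 20 members (median -3.88, adjusted p = 3.99e-08, adjusted p = 0.491 with an estimated correlation), with -3.57 after rescaling, -5.61 in run B and -1.42 in run C. At week 48 limma called 0 of 19, and without control library 3 19 of 20 fell (median -2.10).

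Histone cluster genes, whose transcripts mostly lack a poly(A) tail, rose at week 16 in 35 of 44 members (median 1.12, adjusted p = 3.8e-14, adjusted p = 0.312 with an estimated correlation), with 0.95 after quantile normalization. They were lower at week 4 (median -0.216, adjusted p = 0.00215, adjusted p = 0.672 with an estimated correlation), and at week 48 limma called 0 of 44, and 28 of 44 without control library 3. Immunoglobulin genes rose at week 48 in 10 of 25 members (median 1.38, adjusted p = 3.99e-08, adjusted p = 0.455 with an estimated correlation), and 22 of 33 without control library 3 (median 1.37). They were lower at week 4 (median -0.592, adjusted p = 0.0306) and week 12 (-0.396, adjusted p = 0.0318), both with adjusted p = 0.455 with an estimated correlation, and not called at week 32 (adjusted p = 0.221).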
